A study of Mus musculus with 9 samples.

How the data were processed

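Gene expression was measured on 9 one-colour Agilent arrays, 3 for each of 3 cell groups (SMC, MYF and INM) sorted from fetal mouse lung, with RNA amplified from the sorted cells and labelled with Cy3. The deposited values are log2 signals per array feature, and per the submitters' processing notes limma was used to make them, with no version given. The 9 columns share a minimum of 1.65, a mean of 5.89 and an SD of 3.00, so the values were read as quantile-normalized by the authors. Signals ended near 16 and were compressed there, which narrows differences between very bright genes. Of 62976 features, 733 had an empty cell on at least 1 array (1197 cells), the rule behind these is not stated, and empty cells were left empty. The number of arrays limits the precision.

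Features took their gene symbol from the platform annotation: 43941 had 1 symbol, 0 had several and 19035 had none. Symbols were brought to the current mouse nomenclature with RefSeq gene records, through which 42083 features had a current symbol, 1852 were updated and 6 were kept though not current. Each of 24290 genes was represented by the probe with the highest mean over the 9 arrays. Genes with too few values for a contrast were not tested, which left 24262 to 24273 genes.

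Before the data were examined, the following were set: the groups, the tests, the alternatives, 29 gene lists and the rule for named genes. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with 1 mean per group over all 9 arrays, no covariate, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. The contrasts were SMC minus INM, MYF minus INM, SMC minus MYF and INM minus the mean of SMC and MYF, with an F-test over the 3 groups. The position of INM between MYF and SMC was, for each INM array, the median over the genes called in SMC vs MYF of its distance from MYF divided by the distance of SMC from MYF.

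Lists of at least 5 measured genes were tested with limma's camera at an inter-gene correlation preset at 0.01, adjusted over the 28 lists of a contrast. Genes with an empty cell were left out of camera, 1 gene at most in a list. The lists were smooth muscle contractile genes, contraction receptors and channels, airway smooth muscle, mural cell, alveolar myofibroblast, lipofibroblast and matrix fibroblast, and adventitial fibroblast markers, elastic fibre genes, collagens and basement membrane, and cell cycle genes. Signalling lists covered the hedgehog, WNT, FGF, TGF-beta and BMP, and NOTCH pathways, and a further list held mesenchymal transcription factors. Markers of other cell types covered epithelium, endothelium, leukocytes, erythroid cells, mesothelium, nerve and glia, cartilage, cardiac muscle and skeletal muscle. The rest were dissociation and stress, mitochondrial respiration, ribosomal protein and sex-linked genes, of which the last were given as values. Some genes stand in more than 1 list, such as Krt8, Krt18 and Krt19 in the epithelial and mesothelial lists. The genes of the sort stand in lists too, Pdgfra among alveolar myofibroblast markers and Acta2 among smooth muscle contractile genes.

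Genes were named by a rule in 3 parts. The genes of the sort, Acta2 and Pdgfra, were named in every comparison. For each contrast the 8 most positive and 8 most negative differences were taken among genes past the test whose groups did not overlap, whose brighter group was at or above the median of all genes (6.00) and whose symbol was not a bare gene model. For each list and contrast the 2 most positive and 2 most negative members past the test were taken, or the 2 with the largest absolute difference where none passed. The text gives a part of these. Because 1 array stood apart, the same rule was also applied without SMC replicate 1 (2 SMC, 3 MYF and 3 INM arrays), a repeat made after the values were seen. Genes named in SMC vs INM and in INM against the mean come from that repeat, as 0 genes passed with all 9 arrays.

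Alternatives set beforehand were a replicate block, a further quantile normalization, centring of each array, leaving out genes below the median level, the mean of all probes of a gene, the probe with the largest interquartile range, a trend of the variance on level, array weights, fits of the compared groups alone, probes as the unit, a minimum log2 difference of 1, each array left out in turn, an estimated inter-gene correlation and fry. Added after the arrays were seen, without SMC replicate 1, were the replicate block, the variance trend, the genes below the median level left out, the compared groups alone, the estimated correlation, and each further array left out in turn. Neither scaling alternative moved the median of an array by more than 0.000213. Replicate numbers were not used as pairs, because the labels do not say that a number marks a shared animal, litter or day. Correlations of array deviations within the same replicate number were -0.0770 to 0.0998 over 9 pairs. SMC deviations were taken from a mean that holds SMC replicate 1, so pairs with an SMC array cannot show pairing. Other splits of the arrays into groups of the same sizes were counted, with 100 drawn at a fixed seed where there were more, and spreads of medians and correlations across genes came from 1000 bootstrap draws of genes. The arrays held no other value columns, and background or quality marks of features were not used here.

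The fits were tested on simulated data (23996 genes, 10 runs, 500 changed genes for each size). Each gene had 1 spread, pooled over the groups of the 8 arrays without SMC replicate 1, and SMC replicate 1 was made noisier. The real SMC replicates 2 and 3 correlated less (0.903) than MYF or INM arrays did within their groups (0.956 to 0.970). The recovered shares and false calls may thus not hold for contrasts with SMC. With 9 arrays 7.6% of genes changed by a log2 of 4 were recovered in SMC vs INM, 9.8% in MYF vs INM, 11% in SMC vs MYF and 38.4% in INM against the mean; without SMC replicate 1 these were 71.8%, 76.6%, 72% and 87.4%. At a log2 of 2 without that array, 25.8%, 33.8%, 19.2% and 42.2% were recovered. False calls averaged 0 to 0.1 per run with 9 arrays and 2.7 to 5 without SMC replicate 1. Camera in MYF vs INM without SMC replicate 1 called 10 of 10 lists of 20 genes shifted by a log2 of 1 and 2 of 190 unshifted lists, and a position set at 0.8 along SMC vs MYF was returned as 0.799. Neither was simulated with 9 arrays. The simulated genes varied independently of each other, so the false calls of camera do not cover lists whose genes vary together. Without SMC replicate 1 the estimated correlation of the real cell cycle list was 0.556.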

Results

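RNA of sorted mesenchymal cells from fetal mouse lung was measured on 9 one-colour arrays, 3 arrays in each of 3 groups, and the design gives 3 mice per group. Pregnant mice received 0.1 mg tamoxifen per g body weight at embryonic stage E15.5. RFP-positive cells were sorted at E18.5 after staining for Acta2, the actin of smooth muscle, and for PDGFRA, a receptor of platelet-derived growth factor. The SMC group is Acta2-high and holds smooth muscle of airways and vessels. The MYF group is PDGFRA-high and holds progenitors of alveolar myofibroblasts, the cells that lay elastic fibres in the walls of air sacs. The INM group is low for both proteins, and the labels describe its cells as progenitors of either cell type. The series is about how smooth muscle differentiates in airways, so the comparisons ask what separates the 3 populations and where INM lies between the other groups. Each array gave log2 signals for 62976 features, which covered 24290 genes, and the number of arrays limits the precision of every value below.

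Pdgfra, a gene of the sort, was highest in MYF. It had a log2 signal of 13.52 ± 0.43 in MYF (SD, n = 3), 8.47 ± 0.18 in INM (SD, n = 3) and 6.91 ± 0.03 in SMC replicates 2 and 3 (SD, n = 2), and its signal was 1.98 in SMC replicate 1. Acta2, the other gene of the sort, was high in every group, at 15.34 ± 0.77 in SMC replicates 2 and 3, 13.97 ± 0.09 in MYF and 13.57 ± 0.24 in INM (SD, n = 2, 3 and 3), and 14.77 in SMC replicate 1. Without SMC replicate 1, Acta2 was 1.76 ± 0.38 above INM (SE) and 1.37 ± 0.38 above MYF in SMC, and neither difference passed limma's test (adjusted p = 0.119 and 0.0646). Other probes of these genes gave other signals in SMC replicate 1: 2.84 and 7.95 for Pdgfra, and 3.13, 12.23 and 3.00 for Acta2. The Pdgfra probe at 7.95 had 2.78 and 2.74 in SMC replicates 2 and 3. The Acta2 probe at 3.13 had 13.66 and 11.65 in them.

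SMC replicate 1 stood apart from the other arrays. Its features correlated at r = 0.425 to 0.451 with those of the other 8 arrays, which correlated at 0.864 to 0.970 with each other (28 pairs, across features, which are not independent replicates). SMC replicates 2 and 3 correlated at 0.903 with each other, at 0.915 to 0.938 with the INM arrays and at 0.864 to 0.916 with the MYF arrays. SMC replicate 2 correlated at 0.905, 0.916 and 0.913 with MYF replicates 1, 2 and 3, each above its value with SMC replicate 3. By contrast, MYF arrays reached 0.956 to 0.970 and INM arrays 0.957 to 0.966 within their groups. Counts are given for all 9 arrays and without SMC replicate 1. Differences and gene lists are given without it unless all 9 arrays are named (2 SMC, 3 MYF and 3 INM arrays), a choice made after the arrays were seen.

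**Figure D1:**
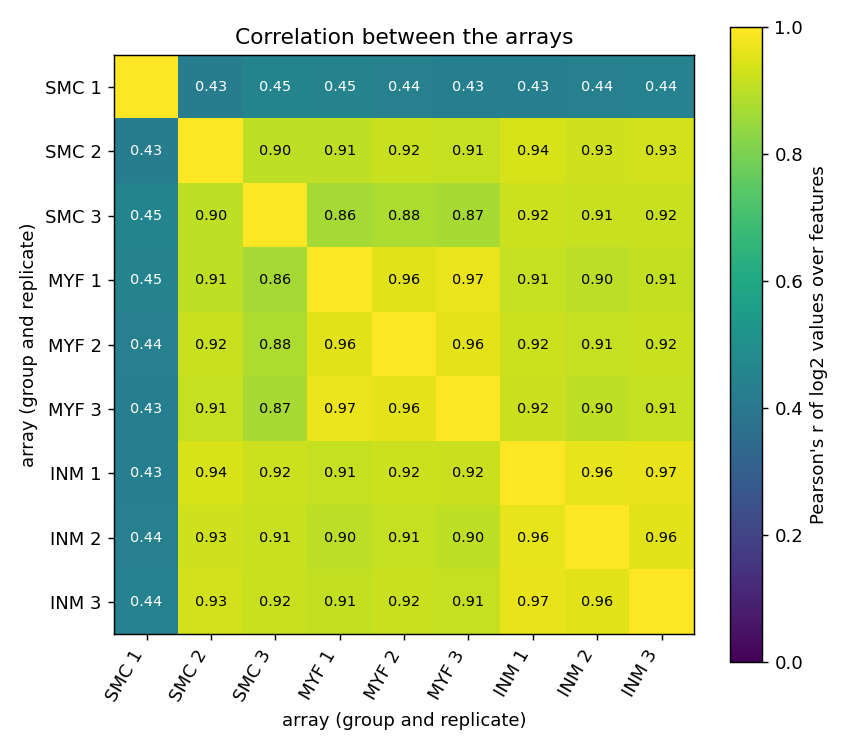
Pearson's r of log2 signals between each pair of arrays, over all features; both axes list the arrays by group and replicate. SMC replicate 1 lies between 0.425 and 0.451 with every other array, and all other pairs lie between 0.864 and 0.970.

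MYF cells had more RNA of alveolar myofibroblast genes than INM cells and less RNA of epithelial genes. Enpp2, which makes lysophosphatidic acid, was higher in MYF by 6.00 ± 0.49 (adjusted p = 0.000557), and the neuropeptide gene Crh by 5.51 ± 0.37 (adjusted p = 0.000344) (log2 difference ± SE, n = 3 and 3). Tgfbi, a matrix protein induced by TGF-beta, rose by 3.82 ± 0.28 and the BMP family member Gdf10 by 5.19 ± 0.46. Pdgfra itself rose by 5.04 ± 0.30 (adjusted p = 0.000299). The collagen gene Col6a4 rose by 7.04 ± 0.94 and the metalloprotease gene Adamts14 by 5.77 ± 0.40. Genes of airway epithelium were lower: the secretory cell gene Cyp2f2 at -7.53 ± 0.85, and Odf3b and Dynlrb2, genes of motile cilia, at -7.70 ± 0.87 and -7.51 ± 1.01. With all 9 arrays 267 of 24264 genes passed the test, 42 higher and 225 lower in MYF, and without SMC replicate 1 the number was 2603, 1056 higher and 1547 lower. All 267 were among the 2603 with the same direction. The 9-array count was 0 after leaving out any 1 of MYF replicates 1, 2 and 3 or INM replicates 1, 2 and 3, 468 without SMC replicate 2 and 545 without SMC replicate 3. With SMC replicate 1 already out, it was 1167 without MYF replicate 1, 1139 without MYF replicate 3, and 1251, 1238 and 1246 without INM replicates 1, 2 and 3.

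**Figure D2:**
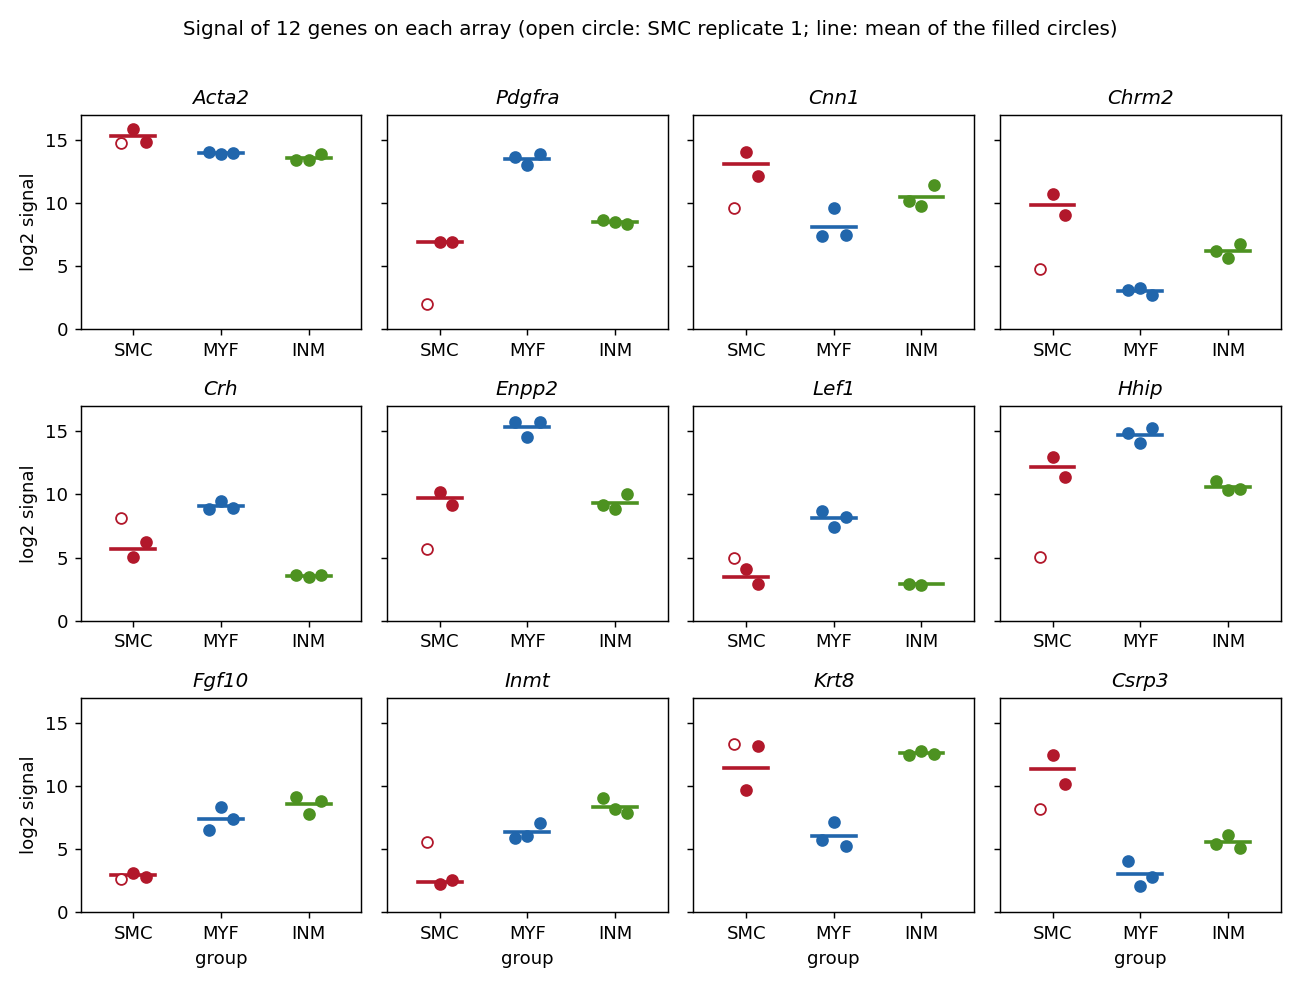
Log2 signal of genes named in the text (y axis) on each array of the SMC, MYF and INM groups (x axis). Circles are arrays, the open circle is SMC replicate 1, and lines are means of the filled circles; Crh is 9.07 ± 0.37 in MYF and 3.56 ± 0.06 in INM (SD, n = 3), and Lef1 has values on 2 of the 3 INM arrays.

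Genes of signalling pathways differed as well. Of 12 hedgehog pathway genes, 9 rose in MYF (10 adjusted over the list alone), led by Hhip (4.11 ± 0.50), which encodes a hedgehog-binding protein, and the transcription factor gene Foxf2 (3.92 ± 0.53). Of 32 WNT pathway genes, 14 rose and 3 fell (17 and 5 adjusted over the list alone). Lef1, a transcription factor of WNT signalling, rose by 5.20 ± 0.50 (n = 3 and 2), the WNT inhibitor gene Wif1 by 5.53 ± 0.65, and the receptor ligase gene Rnf43 changed by -3.98 ± 0.53. The list of 19 alveolar myofibroblast markers had a median difference of 2.44 and passed camera (adjusted p = 7.28e-08, and 0.044 with an estimated correlation). Of its members 11 rose and 1, Fgfr3, fell (12 and 2 adjusted over the list alone). The list holds Pdgfra, a gene of the sort, so its call is not independent of the sort. The hedgehog list had a median of 1.73 (adjusted p = 7.28e-08, and 0.117 with an estimated correlation) and the WNT list 1.05 (adjusted p = 7.31e-05, and 0.117 with an estimated correlation). Smaller medians passed for TGF-beta and BMP genes at 0.55, mesenchymal transcription factors at 0.69, elastic fibre genes at 0.77 and collagens and basement membrane at 0.64. With an estimated correlation their adjusted p were 0.117, 0.117, 0.196 and 0.196. INM also held more RNA of epithelial, endothelial and leukocyte genes. Whether a lower share of mesenchymal RNA in INM gave these smaller medians was not tested.

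Other lists were lower in MYF than in INM. Lipofibroblast and matrix fibroblast markers, genes of lipid-storing and Fgf10-making fibroblasts, had a median of -1.43: 8 of 20 fell and 1 rose (12 and 1 adjusted over the list alone), with the adipogenic factor Pparg at -3.05 ± 0.45 and the lipase gene Lpl at -2.89 ± 0.59 (adjusted p = 0.0242 with an estimated correlation on all 9 arrays and 0.117 without SMC replicate 1). NOTCH pathway genes had a median of -1.27, with Mfng, which modifies NOTCH receptors, at -4.63 ± 0.62 (adjusted p = 0.125 with an estimated correlation). Which cell type the NOTCH RNA came from was not tested. Cell cycle genes had a median of -1.16, and Ccnd1, which drives entry into the cycle, was at -3.53 ± 0.69 (adjusted p = 0.358 with an estimated correlation). Markers of cell types outside the mesenchyme were lower in MYF as well. Epithelial markers had a median of -5.24, and 24 of 25 fell (25 adjusted over the list alone; adjusted p = 0.044 with an estimated correlation). Endothelial markers had a median of -3.99 with 18 of 21 falling, leukocyte markers -3.50 with 13 of 22, and mesothelial markers -3.36 with 7 of 13 (adjusted p = 0.044, 0.196 and 0.044 with an estimated correlation, and 0.119, 0.119 and 0.0191 on all 9 arrays). The mesothelial list shares Krt8, Krt18 and Krt19 (-7.52 ± 0.77) with the epithelial list, so its call is not independent of the epithelial one. Cardiac muscle markers had a median of -1.99 with 7 of 18 falling (adjusted p = 0.215 with an estimated correlation). Mitochondrial respiration genes (-0.53) and ribosomal protein genes (-0.31) passed camera with no member past the test, and dissociation and stress genes had a median of 0.57 (adjusted p = 0.549, 0.196 and 0.196 with an estimated correlation). With the preset correlation 18 of 28 lists passed on all 9 arrays and the same 18 without SMC replicate 1. With an estimated correlation 4 passed in each: alveolar myofibroblast, epithelial and mesothelial markers in both, lipofibroblast markers only on all 9 arrays and endothelial markers only without SMC replicate 1.

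SMC cells differed from MYF cells in single contractile genes, in myofibroblast genes and in markers of heart muscle and other cell types. Cnn1, which encodes calponin, was higher in SMC by 4.95 ± 0.86 (adjusted p = 0.0142) and the intermediate filament gene Des by 4.12 ± 0.98 (adjusted p = 0.0412) (n = 2 and 3). Chrm2, a muscarinic acetylcholine receptor gene of smooth and heart muscle, rose by 6.86 ± 0.55 (adjusted p = 0.00123). Genes of striated and heart muscle were among the largest rises: Csrp3 by 8.32 ± 0.78 (adjusted p = 0.00208), Myl7 by 8.82 ± 0.64 and Myl4 by 7.94 ± 0.63. Mlf1 rose by 8.09 ± 0.42, and by 8.67 ± 0.62 (adjusted p = 0.00643) on all 9 arrays. On the other side Pdgfra was at -6.61 ± 0.33, the enkephalin precursor gene Penk at -6.91 ± 0.40 and Wif1 at -7.45 ± 0.72; on all 9 arrays these were -8.25 ± 1.19 (adjusted p = 0.0309), -8.69 ± 1.29 (adjusted p = 0.0309) and -7.48 ± 0.70 (adjusted p = 0.0105). With all 9 arrays 163 of 24273 genes passed, 92 higher and 71 lower in SMC. Without SMC replicate 1 the number was 1991, 1131 higher and 860 lower, and all 163 were among them with the same direction. The 9-array count was 0 without MYF replicate 1, 2 or 3, and 1, 13 and 7 without INM replicates 1, 2 and 3. It was 1274 without SMC replicate 2, 73 without SMC replicate 3, and 0 when the SMC and MYF arrays were fitted alone (1991 became 626 when they were fitted alone without SMC replicate 1). With SMC replicate 1 already out, it was 4039 without SMC replicate 2, 843 and 817 without MYF replicates 1 and 3, and 1223 and 1327 without INM replicates 1 and 3.

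Of 23 smooth muscle contractile genes, 4 rose in SMC over MYF (7 rose and 2 fell adjusted over the list alone), and the median was 0.78 (adjusted p = 0.00677, and 0.388 with an estimated correlation). On all 9 arrays that list had a median of 0.48 and did not pass (adjusted p = 0.285). Myh11 and Tagln had signals of 14.84 and 13.35 in SMC replicates 2 and 3 and 14.11 and 12.57 in MYF. Smtn and Cald1 were lower in SMC, at 10.99 and 13.48 against 11.54 and 14.39. Cardiac markers rose in the same comparison, so the contractile rises were not told apart from RNA of heart muscle. Alveolar myofibroblast markers had a median of -2.22 with 11 of 19 falling, hedgehog genes -1.96 with 6 of 12, and WNT genes -1.23 with 13 of 32 falling and 1 rising. Their adjusted p with an estimated correlation were 0.0684, 0.136 and 0.104. FGF pathway genes had a median of -1.61 (adjusted p = 0.136 with an estimated correlation): Fgf10, a growth factor for the epithelium, was at -4.47 ± 0.60, and Fgf1 was higher in SMC by 3.61 ± 0.42. Elastic fibre genes were at -1.06 and collagens and basement membrane at -0.90 (adjusted p = 0.136 and 0.136 with an estimated correlation); the elastic fibre protein gene Fbln1 was at -3.82 ± 0.37. Cell cycle genes were higher in SMC by a median of 1.83 and mitochondrial respiration genes by 1.13 (adjusted p = 0.273 and 0.256 with an estimated correlation). With all 9 arrays the medians were -2.80 for alveolar myofibroblast markers, -2.81 for hedgehog, -2.11 for WNT and -2.44 for FGF genes, -1.96 and -1.96 for elastic fibre and collagen genes, 0.93 for cell cycle and -0.55 for mitochondrial respiration genes, which did not pass there (adjusted p = 0.516). Markers of other cell types were higher in SMC than in MYF: cardiac muscle by 6.16 with 16 of 18 rising (16 adjusted over the list alone), epithelium by 3.80 with 25 of 25, endothelium by 3.54 with 16 of 21 and leukocytes by 2.55 with 13 of 22. Their adjusted p with an estimated correlation were 0.136, 0.0714, 0.0684 and 0.143. Mesothelial markers were higher by 1.91 with 5 of 13 rising, and dissociation and stress genes had a median of -0.67 with 7 of 30 falling (-1.79 on all 9 arrays). Their adjusted p with an estimated correlation were 0.118 and 0.143. With SMC replicate 1 kept, the medians of cardiac, epithelial, endothelial, leukocyte and mesothelial markers were 5.02, 3.72, 2.29, 2.6 and 1.62. Further lists passed with medians of -0.68 (mesenchymal transcription factors), -0.44 (TGF-beta and BMP), -0.86 (lipofibroblast markers), 1.06 (skeletal muscle) and 1.08 (NOTCH). Their medians with SMC replicate 1 were -1.76, -1.08, -0.86, 1.06 and 1.05, the last not past camera (adjusted p = 0.08), while mural cell markers (-0.78) passed only there. With the preset correlation 19 lists passed on all 9 arrays and 20 without SMC replicate 1, 17 of them in both with the same direction. With an estimated correlation 1 passed on all 9 arrays, epithelial markers (adjusted p = 0.0295), and 0 without SMC replicate 1.

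Without SMC replicate 1, single genes of matrix fibroblasts were lower and single genes of heart muscle higher in SMC than in INM. Fgf10 was lower in SMC, at -5.62 ± 0.60 (adjusted p = 0.0203), and Inmt, a methyltransferase gene of lung fibroblasts, was at -5.97 ± 0.49 (adjusted p = 0.00939) (n = 2 and 3). The alcohol dehydrogenase gene Adh1 was at -4.34 ± 0.34 and the fatty acid transporter gene Slc27a6 at -4.52 ± 0.56. Genes higher in SMC included Myl2 by 5.93 ± 0.67 (adjusted p = 0.0253) and Csrp3 by 5.77 ± 0.78 (adjusted p = 0.0433), both of heart muscle. The macrophage gene C1qc was higher by 7.45 ± 0.74 (adjusted p = 0.0159) and the chemokine gene Ccl12 by 6.77 ± 0.46 (adjusted p = 0.00939). No gene of 24270 passed limma's test with all 9 arrays (1935 at an unadjusted p under 0.05, smallest adjusted p = 0.0743), and 60 passed without SMC replicate 1, 22 higher and 38 lower in SMC, but none when the SMC and INM arrays were fitted alone. The 9-array count was 4 without SMC replicate 2 and 24 without SMC replicate 3. With SMC replicate 1 out, it was 976 without SMC replicate 2 also, 646 without SMC replicate 3 also, 12, 21 and 11 without MYF replicates 1, 2 and 3, and 5, 11 and 8 without INM replicates 1, 2 and 3. Contractile genes did not pass one by one: the 23 smooth muscle genes had a median of 1.27, 0 passed over all genes and 11 rose adjusted over the list alone (camera adjusted p = 1.97e-08, and 0.22 with an estimated correlation). With SMC replicate 1 kept their median was 0.67 and 0 rose adjusted over the list alone (camera adjusted p = 0.00452). Without SMC replicate 1 the differences of Ldb3 and Des were 4.84 ± 0.78 and 4.05 ± 0.98 (adjusted p = 0.0644 and 0.163). Heart muscle genes such as Myl2 and Csrp3 rose in the same arrays. The contractile differences were therefore not told apart from RNA of heart muscle.

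Lipofibroblast and matrix fibroblast markers were lower in SMC than in INM, with a median of -1.57 and 3 of 20 falling (15 adjusted over the list alone; adjusted p = 0.0139 with an estimated correlation on all 9 arrays and 0.0846 without SMC replicate 1). Cardiac muscle markers were higher by 3.65 with 2 of 18 rising (14 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), and skeletal muscle markers were higher by 0.61 with none past the test over all genes and 5 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). With all 9 arrays the medians of these 3 lists were -2.03, 2.21 and 0.62, with 11 falling, 8 rising and 1 rising adjusted over the list alone. Markers of 3 other cell types were lower in SMC than in INM, with no member past the test: epithelial markers had a median of -1.27, endothelial markers -0.73 and mesothelial markers -1.15 (camera adjusted p = 5.64e-07, 0.00477 and 0.0171, and 0.22, 0.302 and 0.22 with an estimated correlation). On all 9 arrays these medians were -1.25, -1.60 and -1.14, and the mesothelial list did not pass (adjusted p = 0.0903). Of 22 leukocyte markers 1, C1qc, was higher in SMC past the test (3 adjusted over the list alone), with a median of -0.15 and a mean of 0.26. Airway smooth muscle markers were higher by 1.00 (adjusted p = 0.0033, and 0.337 with an estimated correlation); Myocd, which switches on contractile genes, was at 3.60 ± 0.71 (adjusted p = 0.104) and did not pass. Actc1 stands in both the airway smooth muscle and the cardiac list. Mural cell markers of pericytes and vascular muscle had a median of -0.55 and contraction receptors and channels 0.40 (adjusted p = 0.22 and 0.608 with an estimated correlation). On all 9 arrays airway smooth muscle markers (median 1.14, adjusted p = 0.161) and contraction receptors and channels (0.19, adjusted p = 0.524) did not pass, and mural cell markers had a median of -1.69. Cell cycle genes had a median of 0.50 and mitochondrial respiration genes 0.62 (adjusted p = 0.776 and 0.443 with an estimated correlation), and on all 9 arrays the direction turned, to -0.72 and -0.88. Smaller medians passed for FGF (-0.60) and WNT genes (-0.36), collagens and basement membrane (-0.31) and ribosomal protein genes (-0.23), which had -1.61, -0.96, -1.38 and -0.64 on all 9 arrays. Elastic fibre (-1.26), hedgehog (-0.90) and dissociation and stress genes (-1.17) passed only with SMC replicate 1. With the preset correlation 15 lists passed on all 9 arrays and 16 without SMC replicate 1, 11 of them in both; with an estimated correlation 1, the lipofibroblast list, and 0 passed.

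Genes of airway epithelium and of matrix fibroblasts were higher in INM than the mean of both other groups, the epithelial genes with a larger difference to MYF than to SMC. Cyp2f2 of airway secretory cells was higher by 4.80 ± 0.77 (adjusted p = 0.0177), the water channel gene Aqp5 by 4.68 ± 0.77 and the chemokine gene Ccl3 by 4.32 ± 0.38 (adjusted p = 0.00391) (n = 3 against 2 and 3). In SMC vs INM alone these 3 genes did not pass, at -2.08 ± 0.95, -3.98 ± 0.96 and -1.80 ± 0.48 (adjusted p = 0.424, 0.163 and 0.2). Among mesenchymal genes Inmt was higher by 3.98 ± 0.39, Fgf10 by 3.38 ± 0.48, and the fibroblast transcription factor genes Tcf21 by 1.95 ± 0.39 and Meox2 by 1.88 ± 0.34. Lower in INM were Myocd at -3.32 ± 0.58, Smtn, which encodes an actin-binding protein of smooth muscle, at -1.44 ± 0.31, and Hhip at -2.83 ± 0.45. The Y-linked gene Eif2s3y was at -6.66 ± 0.55 (adjusted p = 0.00391). With all 9 arrays no gene of 24262 passed limma's test (1801 at an unadjusted p under 0.05, smallest adjusted p = 0.0539). Without SMC replicate 1, 810 passed, 631 higher and 179 lower in INM. The 9-array count was 28 without SMC replicate 2 and 327 without SMC replicate 3. With SMC replicate 1 out it was 1482 without SMC replicate 2 also, 1826 without SMC replicate 3 also, 442, 710 and 377 without MYF replicates 1, 2 and 3, and 216, 141 and 143 without INM replicates 1, 2 and 3.

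Lipofibroblast and matrix fibroblast markers were higher in INM by a median of 1.73, and 11 of 20 rose (17 adjusted over the list alone; adjusted p = 0.0349 with an estimated correlation). Smooth muscle contractile genes had a median of -0.73 with 2 of 23 falling (4 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), and alveolar myofibroblast markers -1.10 with 8 of 19 falling and 2 rising (adjusted p = 0.0605 with an estimated correlation). Epithelial markers were higher by 3.32 with 18 of 25 rising, endothelial markers by 2.31 with 14 of 21 and mesothelial markers by 2.24 with 4 of 13 (adjusted p = 0.0349 with an estimated correlation for each of the 3 lists, and 0.00508, 0.217 and 0.027 on all 9 arrays). The mesothelial call is again not independent of the epithelial one, as these lists share Krt8, Krt18 and Krt19. Leukocyte markers were higher by 1.68 with 3 of 22 rising and 1 falling (camera adjusted p = 0.00365, and 0.465 with an estimated correlation), and by 1.73 on all 9 arrays. Of 25 epithelial markers 0 passed in SMC vs INM (median -1.27) and 24 in MYF vs INM (-5.24). The medians on all 9 arrays of the lipofibroblast, contractile, alveolar myofibroblast, epithelial, endothelial and mesothelial lists were 1.88, -0.59, -0.92, 3.44, 2.75 and 2.36. Hedgehog genes had a median of -0.80 with 2 of 12 falling (3 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), and did not pass on all 9 arrays (median -0.46, adjusted p = 0.0742). NOTCH pathway genes were higher by 0.72 (adjusted p = 0.243 with an estimated correlation), and by 1.36 on all 9 arrays (camera adjusted p = 0.00128). Further lists passed without SMC replicate 1 with medians of -0.85 (airway smooth muscle markers), 0.58 (cell cycle), -0.38 (mesenchymal transcription factors), 0.31 (ribosomal proteins) and -0.30 (TGF-beta and BMP). With that array kept, the cell cycle (1.20) and ribosomal lists (0.60) still passed and the other 3 did not, while mural cell markers (1.04) passed only there. With the preset correlation 11 lists passed on all 9 arrays and 14 without SMC replicate 1, 10 of them in both. With an estimated correlation lipofibroblast, epithelial and mesothelial markers passed in both, and endothelial markers only without SMC replicate 1. Over the 3 groups together limma's F-test called 203 genes on all 9 arrays and 2476 without SMC replicate 1. The 9-array count was 0 without MYF replicate 1, 2 or 3 and without INM replicate 1 or 3, 3 without INM replicate 2, 926 without SMC replicate 2 and 498 without SMC replicate 3.

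**Figure D3:**
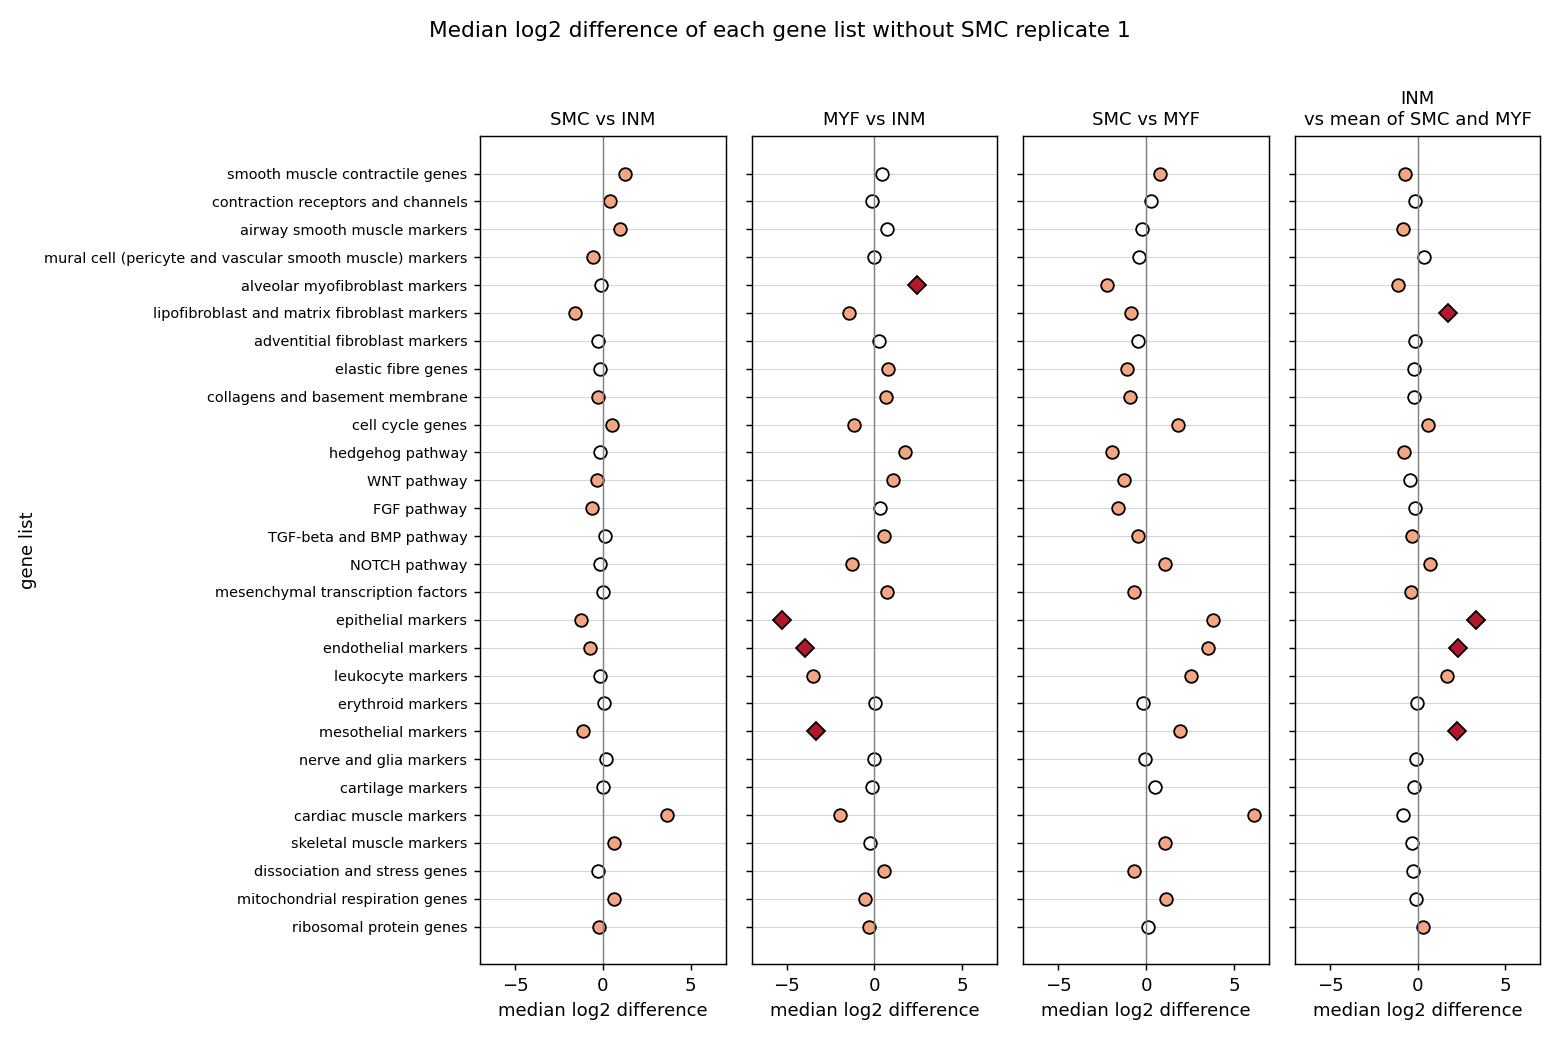
Median log2 difference (x axis) of each gene list (y axis) in the 4 comparisons, without SMC replicate 1. Filled symbols passed camera at the preset correlation and diamonds also passed with an estimated correlation; epithelial markers are at -5.24 in MYF vs INM and 3.32 in INM against the mean of the other groups.

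Along the genes that separate SMC from MYF, INM lay nearer to SMC on all 9 arrays, but nearer to MYF without SMC replicate 2. On a scale with 0 at MYF and 1 at SMC, the 163 genes called on all 9 arrays put INM at 0.801 ± 0.0424 (mean and SD of 3 INM arrays). The mean level of INM lay between both groups for 102 of the 163 genes and beyond SMC for 55. The 92 genes higher in SMC gave 0.983 ± 0.0342 and the 71 lower in SMC 0.659 ± 0.0160, and Pdgfra, at 8.47 in INM, lay between 6.91 in SMC replicates 2 and 3 and 13.52 in MYF. Without SMC replicate 1, 1991 genes gave 0.806 ± 0.0234. Without SMC replicate 2 the position was 0.415, over 1274 genes called with SMC replicate 1 as 1 of the 2 SMC arrays. Genes of other cell types counted in it, since 25 of 25 epithelial and 16 of 18 cardiac markers were among the 1991 genes.

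Other lists had small medians or went both ways without SMC replicate 1. Adventitial fibroblast markers, genes of the sheath around vessels and airways, had medians of -0.28, 0.24, -0.43 and -0.16 in SMC vs INM, MYF vs INM, SMC vs MYF and INM against the mean, none past camera without SMC replicate 1 (the means were -0.002 in MYF vs INM and 0.18 in INM against the mean, of the other sign). On all 9 arrays this list was lower in SMC and passed, at -1.30 in SMC vs INM and -1.57 in SMC vs MYF (camera adjusted p = 0.00283 and 0.0115). Those calls ended without SMC replicate 1, and also with an estimated correlation on all 9 arrays (adjusted p = 0.453 and 0.430). Dpp4 was at -6.12 ± 0.53 (adjusted p = 0.000692) in MYF vs INM. Erythroid markers had medians of 0.06, 0.02, -0.18 and -0.03 with no member past the test, and means of -0.42 in SMC vs INM and 0.14 in INM against the mean, of the other sign. Nerve and glia markers had medians of 0.18, -0.04, -0.04 and -0.10 and cartilage markers -0.0014, -0.15, 0.52 and -0.22, none past camera. The means of nerve and glia markers were 0.71 in SMC vs MYF and 0.23 in INM against the mean, and that of cartilage markers in INM against the mean was 0.20. Single members differed in MYF vs INM, with Erbb3 of the nerve and glia list at -5.36 ± 0.39 and Cytl1 of the cartilage list at -3.75 ± 0.67. Which cell type their RNA came from was not tested. Airway smooth muscle markers in SMC vs MYF had a median of -0.21 but a mean of 0.79, with Chrm2 among 2 that rose and 2 that fell, and contraction receptors and channels in MYF vs INM had a median of -0.14 and a mean of 0.08. Camera took the sign of the mean in both. The same held for alveolar myofibroblast markers in SMC vs INM (-0.10 and 0.05), hedgehog genes (-0.15 and 0.03) and leukocyte markers (-0.15 and 0.26) there, and for FGF genes in INM against the mean (-0.14 and 0.28), none of which passed.

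The Y-linked genes Eif2s3y and Uty were lower in INM than in both other groups. Sex-linked genes, 4 of 5 measured, were not tested as a list, and the labels give no sex of the mice. Eif2s3y was higher than in INM by 7.45 ± 0.76 (adjusted p = 0.00838) in MYF on all 9 arrays and by 5.86 ± 0.68 in SMC, Uty by 4.09 ± 0.41 and 3.39 ± 0.45, and Kdm5d by 1.15 ± 0.27 and -0.04 ± 0.30, whereas Xist, the gene of X inactivation, was at -1.71 ± 1.28 and -0.83 ± 1.43. The Y-linked difference went with every comparison that holds INM.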

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

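The tests on brighter probes and on the order of the features were chosen only after SMC replicate 1 had been seen to stand apart.

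The median correlation of SMC replicate 1 with the other arrays was 0.436, and this array was marked because its gap to the next array took 0.932 of the range of the 9 arrays' medians; chance alone marks about 1 in 20 such groups. Probes for the same gene moved together less in this array than in real differences: the deviations of 2 probes of a gene, SMC replicate 1 against the other SMC arrays, correlated at r = 0.256 (10851 genes, across genes, which are not independent replicates), against 0.533 for MYF replicate 1 minus INM, a ratio of 0.481 ± 0.0196 (bootstrap SD). That pattern is consistent with signal lost or gained probe by probe, as amplification of little or degraded RNA could give, although the ratio lay under the bound of 0.5 by less than its bootstrap SD. RNA of another tissue or a mislabelled sample would move both probes of a gene alike, and at probes above a log2 of 8 the correlation was 0.158 (1731 genes) against 0.757, a ratio of 0.209 ± 0.0326, which argues against it as the whole cause. Features out of order in the column would leave some block without correlation, yet the lowest of 21 blocks of 3000 consecutive features had r = 0.404 with the mean of the other arrays. No biological explanation was tested, since nothing in the design sets this mouse or its cells apart, and RNA quality values were not used here.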

How the results depend on the processing

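Alternatives run without SMC replicate 1, other than leaving out that array alone, were chosen after seeing the data; for the changes below the cause was not tested, except that array weights gave SMC replicate 1 a weight of 0.0320. A further quantile normalization, centring and a minimum log2 difference of 1 left the 4 counts of genes with all 9 arrays as they were. The minimum was not applied to the F-test, and without SMC replicate 1 it took the 2603 genes of MYF vs INM to 2569. In the order SMC vs INM, MYF vs INM, SMC vs MYF and INM against the mean, the 0, 267, 163 and 0 genes became 611, 4724, 4272 and 1910 with array weights, and 3, 441, 355 and 33 with the probe of largest interquartile range. The mean of all probes gave 450 genes in MYF vs INM and 52 in INM against the mean, and probes as the unit gave 264 in SMC vs MYF. The compared groups alone gave 3632 genes in MYF vs INM and 0 in SMC vs MYF. The F-test's 203 genes became 313, 381 and 5696 with the mean of probes, the probe of largest interquartile range and array weights. Without SMC replicate 1 the variance trend gave 117, 3315, 2979 and 1202 genes, leaving out genes below the median level 45, 2823, 2540 and 788, and the compared groups alone 3632 in MYF vs INM and 626 in SMC vs MYF.

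With a replicate block, MYF vs INM gave 0 genes, SMC vs MYF 1 and the F-test 0, and the position was 0.738; without SMC replicate 1 the replicate block gave 1578 genes in MYF vs INM, 769 in SMC vs MYF, 377 in INM against the mean and 0 in SMC vs INM.

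The position of 0.801 became 0.870 without genes below the median level, 0.705 with the probe of largest interquartile range and 0.682 with array weights. No position could be had with the compared groups alone or without MYF replicate 1, 2 or 3, as no gene passed in SMC vs MYF. Lists passing camera numbered 15, 18, 19 and 11 in the same order. With an estimated correlation they were 1, 4, 1 and 3 (0, 4, 0 and 4 without SMC replicate 1), with fry 1 in SMC vs INM, 6 in MYF vs INM and 3 in INM against the mean, without genes below the median level 8 in SMC vs INM, and with the probe of largest interquartile range 7 in INM against the mean. Leaving out 1 array, or 1 array beside SMC replicate 1, gave 0 to 976 genes in SMC vs INM, 0 to 3632 in MYF vs INM, 0 to 4039 in SMC vs MYF, and 0 to 1826 in INM against the mean. Leaving out 1 array alone gave 0 to 2476 genes in the F-test, a position of 0.415 to 0.806, and 15 to 17, 13 to 18, 16 to 20 and 10 to 14 lists. Where 1 SMC array was left, it was assumed to vary like the arrays of the other groups. Of 63 list calls none reversed under an alternative; 14 were lost without genes below the median level, 13 with the probe of largest interquartile range, 8 with array weights, 7 without SMC replicate 1 and up to 7 without another array. Of 56 calls of named genes with all 9 arrays none reversed either, and 0 kept their call without MYF replicate 1, 2 or 3, 1, 6 and 3 without INM replicates 1, 2 and 3, 1 with the replicate block and 29 with the compared groups alone. It was kept by 41 without SMC replicate 3, by 49 with the mean of all probes, by 53 with the variance trend and by 54 with the probe of largest interquartile range. Background values were not used here, so signal over background is unknown, and signals near 16 are compressed.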

Other observations

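The tests of epithelial cells in the INM sort and of heart muscle cells in the SMC sort, and the gaps without erythroid markers and among markers with room to rise (5 further lists included), were chosen only after these markers had been seen to differ. Unless all 9 arrays are named, values are without SMC replicate 1.

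Single genes of contraction, matrix and growth factor response differed between MYF and INM, while 3 of these lists did not pass camera. Contractile genes had 4 of 23 rising (adjusted p = 0.129), contraction receptors and channels 2 rising and 2 falling of 24 (adjusted p = 0.939) and FGF pathway genes 5 rising and 2 falling of 19 (adjusted p = 0.346). Smtn rose in MYF by 1.71 ± 0.34 (adjusted p = 0.0183) and Myh11, the smooth muscle myosin gene, by 1.64 ± 0.43 (adjusted p = 0.0489) (log2 difference ± SE, n = 3 and 3). Ednrb, a receptor of endothelin, rose by 3.67 ± 0.35, whereas Chrm2 was at -3.19 ± 0.49. The laminin chains Lamc1, Lama2 and Lamc3 rose by 2.44 ± 0.29, 2.39 ± 0.58 and 3.81 ± 0.58, and Lama5 was at -2.06 ± 0.37. Spry1, an inhibitor of FGF signalling, rose by 2.71 ± 0.37 and the transcription factor gene Etv1 by 3.38 ± 0.52, while Fgf1 was at -4.38 ± 0.38. Among transcription factors Hoxb6 rose by 4.26 ± 0.61, and in SMC vs MYF Tbx3 was at -4.46 ± 0.71 and Hand2 at 2.70 ± 0.61 (n = 2 and 3). Among leukocyte genes Csf1r, a receptor of macrophages, was 12.95 ± 0.18 in MYF and 11.90 ± 0.05 in INM (SD, n = 3) and rose in MYF by 1.04 ± 0.24 (adjusted p = 0.0333), although 13 of 22 leukocyte markers fell. A difference in the sex of the mice between groups was not tested and stays open for every comparison with INM, since Eif2s3y had a log2 signal of 2.97 ± 0.05 in INM and 10.41 ± 0.84 in MYF (SD, n = 3).

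Epithelial markers were higher in INM than in MYF with a share of 0.96 past the test (24 of 25), a count that restates the pattern and so does not support any source of it. RNA of epithelial cells in the INM sort stays open. Ager, of flat alveolar cells, had a log2 signal of 15.12 ± 0.21 in INM and 10.61 ± 0.66 in MYF (SD, n = 3). Sftpc, a surfactant protein gene, had 15.90 ± 0.11 and 11.89 ± 1.46. Scgb3a2 of airway secretory cells had 15.991 and 10.003, and Foxj1 of ciliated cells 11.38 and 3.17. The median signal of the 25 markers was 11.3, 11.7 and 11.4 on INM replicates 1, 2 and 3. On MYF replicates 1, 2 and 3 it was 6.5, 5.6 and 5.9. Such a set of markers of several epithelial cell types argues against a difference of the sorted mesenchymal cells as the whole source. Whether such a difference added to it was not tested. The gate for RFP would remove cells without RFP, and the labels name no stain against epithelium. A lower share of PDGFRA-high cells in INM could raise markers of every other cell type by the same amount. Epithelial and erythroid markers had the highest and lowest median INM minus MYF difference of 4 cell type lists, 5.26 ± 0.474 apart (bootstrap SD). That gap argues against an equal rise only. A lower share that raised each cell type by its own amount, or not at all where a type was absent, would also give a gap and stays open. Erythroid markers are weak evidence by themselves, as 7 of 13 were below the median level and only 3 of the others had room on the scale to rise by 3.50, but among members above that level with such room epithelial markers also lay 2.82 ± 0.989 above 14 cardiac and 5.28 ± 0.901 above 10 skeletal muscle markers (with wider spreads 4.69 ± 1.58 above cartilage, 5.3 ± 3.13 above nerve and glia and 1.53 ± 2.09 above mesothelial markers). A rise of epithelial, endothelial and leukocyte cells together stays open, as the gap among these 3 lists was 1.75 ± 1.07.

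Cardiac markers were higher in SMC than in MYF with a share of 0.889 past the test (16 of 18), which again restates the pattern and does not support any source of it. Myh6, the myosin of heart muscle, was 15.48 ± 0.73 in SMC replicates 2 and 3 (SD, n = 2), 7.63 ± 1.72 in MYF and 12.96 ± 0.41 in INM (SD, n = 3), and Myl4 was 15.13 ± 1.24, 7.19 ± 0.75 and 11.19 ± 0.53, while the atrial hormone gene Nppa was 5.50 ± 1.13, 6.65 ± 0.41 and 5.94 ± 0.71. A rise of striated muscle genes in general is argued against by the gap of 5.10 ± 1.01 (bootstrap SD) between the medians of cardiac (6.16) and skeletal (1.06) markers. RNA of heart muscle cells in the SMC sort and heart muscle in the walls of lung veins stay open. A difference of the sorted smooth muscle itself was not tested. The rise took in the heart sarcomere genes Tnni3 (13.53 in SMC replicates 2 and 3, 6.25 in MYF) and Mybpc3 (11.16 and 6.17). It also took in the heart transcription factor gene Nkx2-5 (7.74 and 2.55). Such a set of heart genes argues against smooth muscle as the whole source, though Nppa did not rise. The gate for RFP would remove heart muscle cells without RFP.

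Other splits of the arrays into groups of the same sizes were counted for each count of genes or lists. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In SMC vs INM 10 of the 10 splits gave as many genes (real 0, highest other 0), in MYF vs INM 1 (real 267, highest other 0) and in SMC vs MYF 1 (real 163, highest other 0). For lists passing camera 1 of 10 splits gave as many in each of these comparisons, with real values of 15, 18 and 19 and highest others of 13, 14 and 15. For the F-test 1 of 100 splits, the real one, gave as many genes (203, highest other 76). Without SMC replicate 1 it was again 1 of 100 (2476, highest other 1339). An absence of any grouping was excluded in this way. Both of these highest other splits kept the 3 MYF arrays together and mixed SMC with INM arrays. The test therefore does not show that SMC stands apart from INM. For genes that set INM apart, 100 of 100 splits gave as many as the real 0 and the highest was 250, in the split that set the 3 MYF arrays apart; without SMC replicate 1, 2 of 100 did (real 810). The higher of these, 3321, again set the 3 MYF arrays apart and points to a structure of the samples, in which MYF differs from SMC and INM. For lists that set INM apart 61 of 100 splits gave as many (real 11, highest other 18), so chance was not excluded there.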
